A study of Mus musculus with 4 samples.

How the data were processed

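The data are RNA-seq libraries from 4 cultures of mouse small intestinal organoids, 1 library per group, harvested 24 hours after crypts were seeded. Groups were taken from the genotype and title of each sample: Yap+/-, Yap-/-, YapTg without doxycycline and YapTg with doxycycline. Per the labels, total RNA was extracted on columns and libraries were prepared with an Illumina TruSeq RNA kit. The submitters' processing notes name CASAVA 1.8, FastQC and TopHat 1.4.1 with the mm9 build of the mouse genome. The read counter, annotation release, strand setting, treatment of reads with several matches, and filters are not given in the sources used here.

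The deposited table holds 22632 genes, with an Ensembl identifier, a symbol and 4 columns of values, all 4 of which were used (0 left unused). The deposited unit was identified as RPKM from the values, since no header names it. Each column sums to between 255064 and 302835. Low values of a gene stand in ratios of small whole numbers times a constant per pair of libraries, as whole reads divided by gene length and library total would. Whether reads or read pairs were counted is not stated. Library totals were solved from gene lengths in GENCODE M21 (GRCm38): 4677 of 12867 genes gave the same total, and the 4 totals came out within 0.0093 of whole numbers. A whole gene length was then sought for each gene that makes its reads whole (within 0.05) in every library. Such a length was found for 17378 of 17378 genes above 0, and for 6679 it equalled the GENCODE M21 length. Several lengths can fit a gene, since multiples of a fitting length also fit. The candidate nearest to the GENCODE M21 length was taken, or the shortest for a gene without one, so read numbers rest on the annotation. For 4091 genes the choice was neither the GENCODE M21 length nor the shortest candidate, and their read numbers are less certain. The remaining 5254 genes are listed at 0 in all 4 libraries. No coordinates are printed, because the annotation at hand is of another build than mm9. It was used for lengths, for which genes share a chromosome and for which genes lie within 30 Mb of Yap1.

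The design fixed before the data were examined foresaw counts, for which values would have been rescaled, or RPKM used as deposited; the latter applied. RPKM values were used as deposited. Log2 ratios were computed on RPKM plus a pseudocount of 1, which understates the difference of low genes. Folds in the text are ratios of RPKM without the pseudocount. A gene counted as higher or lower when the log2 ratio reached 2-fold and the higher library reached 1 RPKM. With 1 library per group no test was made and no p-value computed. Each fold has an exact conditional binomial (Clopper-Pearson) 95% interval from the recovered reads. PCR copies are not independent molecules, so these intervals cover counting error only. A gene with 0 reads is given a bound from 3 reads. At 1 RPKM a gene of 2 kb has between 89.9 and 151 reads in these libraries. The comparisons were Yap-/- over Yap+/-, YapTg with over without doxycycline, and Yap+/- over YapTg without doxycycline as a yardstick between reference libraries.

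A total of 24 gene lists were fixed before the data were examined: YAP/TEAD targets, Hippo components, stem cell, Paneth, goblet, enteroendocrine, tuft and enterocyte markers, Wnt targets, alpha-defensin genes, fetal-like and regenerative genes, EGF receptor ligands, cell cycle, p53, Notch, integrated stress response, immediate early and heat shock, interferon, NF-kappaB, stromal, immune, red blood cell, housekeeping and sex-linked genes. Pla2g2a and Xist had no row under their names. For each list with at least 3 members at the floor, the median log2 ratio was set among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A median outside the 2.5 to 97.5 percentile was taken to stand apart, as a description of these libraries. Marker lists describe whole organoid libraries and not sorted cells, and several lists share members with tissue-wide epithelial expression. Symbols are those of the table, and 20750 identifiers (91.7%) matched a table of current names; 129 symbols were shared by more than 1 identifier.

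Genes were named by a rule fixed before the data were examined. It takes Yap1; the 6 highest and 6 lowest log2 ratios among genes at 5 RPKM and 20 reads or more, without predicted genes and multi-copy families; and the 2 members furthest from 0 of each core list, or of another list that stands apart. For opposite directions it takes the 6 genes per direction with the largest smaller ratio. Genes named outside the rule are marked in the text, and the genes in the plot of marker values were chosen after their values were seen.

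The alternatives were pseudocounts of 0.1 and 5, no floor and a floor of 5 RPKM, median-ratio and upper-quartile scaling, a 4-fold threshold, a counting interval that excludes 1, lists without their most changed member, and unmatched random lists. A restriction to established gene names and the removal of the chromosome of Yap1 were added after the data were seen.

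The rules were tested on simulated data drawn with counting error only from the mean levels and totals, with 200 changed genes in each run. For the Yap loss pair (10591 genes) the size rule found 99.4% of genes simulated at 3-fold, 100% at 5-fold and 0% at 1.5-fold, and for the induction pair (10875 genes) 100%, 100% and 0.290%. Of the unchanged genes 0.0208% and 0.0221% were called. The counting interval held the true fold in 95.2% and 95.4% of 1000 cases each. Random lists of 15 genes without a shift stood apart in 4.75% and 6.25% of 400 trials, and with a log2 shift of 0.5 in 100% of both. Simulated genes varied independently, while genes of a real list can vary together, so real lists can stand apart more often. Between the reference libraries, for example, the cell cycle list lay at percentile 0 and the enteroendocrine list at percentile 100. Read recovery over 4951 simulated genes returned 4 of 4 library totals exactly and the right reads in every library for 97.5% of genes, and 0.100% of 1000 genes with jittered values came out whole. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.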

Results

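RNA was sequenced from small intestinal organoids, which are epithelial cultures grown from isolated mouse crypts, 24 hours after the crypts were seeded. There were 4 libraries and 4 groups, with 1 library in each. Yap+/- organoids carried 1 working copy of Yap1, the gene for the transcriptional co-activator YAP that the Hippo pathway restrains. Yap-/- organoids had lost both copies in the epithelium through Villin-Cre. YapTg organoids carried a wild-type Yap transgene switched on by doxycycline, and were grown without or with the drug. The library totals behind the deposited values came out at 56926423 reads for Yap+/-, 67716822 for Yap-/-, 44934170 for YapTg without doxycycline and 75269003 for YapTg with doxycycline. Genes held 87.9%, 92.5%, 90.3% and 91.0% of these reads in the same order. Between 10530 and 10722 genes per library reached 1 RPKM (reads scaled by gene length and library total). No group had a replicate, so no difference below has a replicate check or a p-value, and the intervals given cover counting error only.

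Yap1 itself followed the labels. It was at 16.7 RPKM in the Yap+/- library and 3.35 RPKM in the Yap-/- library, 4.99-fold lower (95% interval 4.74 to 5.25). It was at 25.1 RPKM in uninduced and 1039 RPKM in induced YapTg organoids, 41.4-fold higher (95% interval 40.6 to 42.3), where it took 0.951% of all reads in genes. The species and sequence of the transgene are not given in the labels, so this fold over the mouse gene model is a coarse check. The value covers the whole gene model, so the 1890 Yap1 reads left in the Yap-/- library are not assigned to deleted or kept exons. Wwtr1, which encodes the related co-activator TAZ, was low in every library, with 0.390 RPKM in Yap+/-, 0.127 in Yap-/-, 0.526 in uninduced and 3.66 in induced organoids. It was named after its values were seen.

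**Figure D1:**
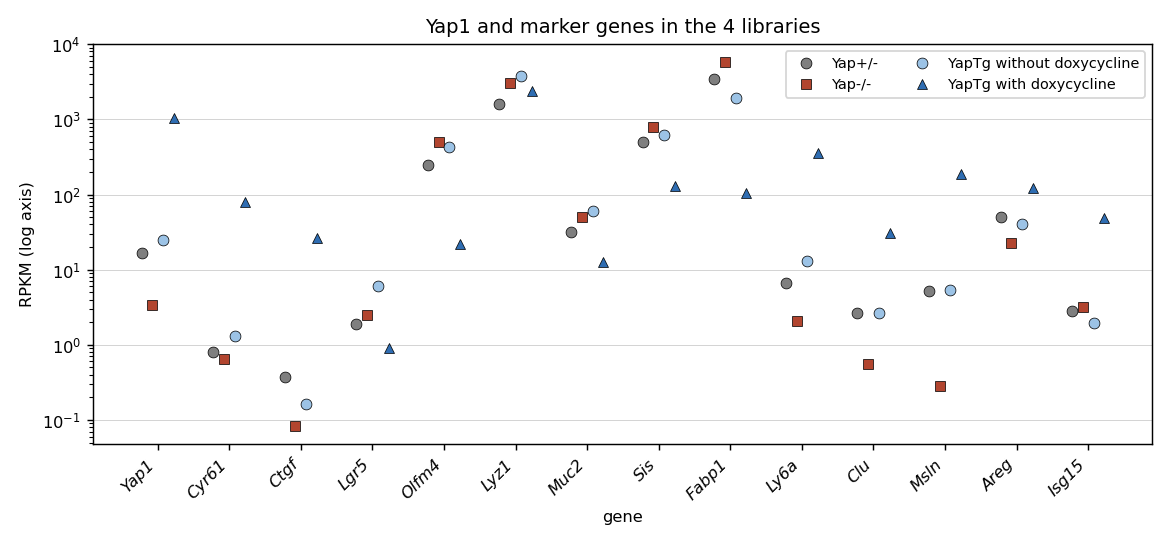
RPKM on a log axis for Yap1 and 13 marker genes, with a symbol for each of the 4 libraries. Yap1 spans 3.35 to 1039 RPKM, and Msln, Ly6a and Clu are lowest in the Yap-/- and highest in the induced library.

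Loss of Yap asks which transcripts of young organoids need the gene. Without Yap, fetal-like and regenerative epithelial genes such as Msln, Clu and Ly6a were lower (median log2 ratio of the list -1.21). Markers of differentiated lineages and of stem cells were slightly higher, with list medians from 0.24 to 0.86. Few genes differed by much. Of 10710 genes at 1 RPKM or more in either library, 36 were at least 2-fold higher and 61 at least 2-fold lower in Yap-/- organoids. The split was 28 and 69 after median-ratio scaling, and 17 and 48 among established gene names. The median absolute log2 ratio was 0.09. The 97 genes are fewer than the 200 that separated the Yap+/- library from the uninduced YapTg library, a pair with neither full loss nor induction. That pair also differed in organoid line and in reads of Y-linked genes, so the 200 genes are not a spread between replicates.

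The gene furthest lower in Yap-/- organoids was Cyp1a1, a drug-metabolising enzyme under the aryl hydrocarbon receptor. It was at 14.4 RPKM in Yap+/- and 0.0564 RPKM in Yap-/- organoids, a 256-fold difference (95% interval 139 to 535). Cyp1a1 was also low in the YapTg libraries, at 0.255 RPKM uninduced and 0.665 RPKM induced, so only the Yap+/- library had a high level. Isx, an intestinal homeobox transcription factor, was 24.7-fold lower (10.6 against 0.429 RPKM). Sprr2a2 and Sprr2a3, small proline-rich proteins of the cornified envelope, were 7.70-fold and 6.10-fold lower, and these near-identical copies can share reads. Msln, the mesothelial and fetal epithelial surface protein, was 18.0-fold lower, and Il1rn, the interleukin-1 receptor antagonist, 7.52-fold lower. At the other end, the sialyltransferase gene St3gal4 was 4.42-fold higher (230 against 52.2 RPKM). Nox1, a superoxide-producing oxidase of the crypt, was 3.53-fold higher, and the ubiquitin ligase gene Mid1 3.22-fold. Scarb1, Bcmo1 and Enpp7, which act in the uptake and breakdown of lipids and carotenoids, were 2.85-fold, 2.57-fold and 2.52-fold higher. St3gal4 lies on the same chromosome as Yap1 in the GRCm38 annotation.

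The fetal-like and regenerative list had 15 members above the floor of 1 RPKM. All 15 were lower in Yap-/- organoids, 9 of them at least 2-fold, with a median log2 ratio of -1.21. That median lay below those of all 10000 random lists of the same size and level. Besides Msln and Il1rn, the stem cell antigen gene Ly6a was at 6.67 RPKM in Yap+/- and 2.09 RPKM in Yap-/- organoids, the annexin gene Anxa3 at 19.1 and 6.23 RPKM, and Clu, a marker of damage-induced stem cells, at 2.61 and 0.550 RPKM. Ly6a, Anxa3 and Clu were named here after their values were seen. EGF receptor ligands were lower as well, with a median of -0.64 at the 0 percentile. Areg was 2.24-fold lower and the only ligand of 5 past 2-fold, and Ereg was 1.92-fold lower.

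Classical YAP/TEAD target genes showed less. Of 24 listed genes, 9 reached the floor, and 7 of those 9 were lower in Yap-/- organoids (mean log2 ratio -0.34). The list median of -0.05 stayed inside the range of random lists (percentile 4.36). At least 2-fold lower were 2 genes, and 0 were at least 2-fold higher. The 2 were F3, which encodes tissue factor, at 18.4 and 6.31 RPKM, and the junction gene Ajuba (under its older symbol Jub) 4.12-fold lower. Most other listed targets had little expression to lose. Ctgf stood at 0.374 RPKM in Yap+/- and 0.0830 RPKM in Yap-/- organoids, 4.50-fold lower (95% interval 2.46 to 8.79). Cyr61 was at 0.814 and 0.655 RPKM, 1.24-fold lower, and its interval of 0.921 to 1.68 includes no difference. Ctgf and Cyr61 lay below the floor in this pair and were named after their values were seen.

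Most lineage and stem cell markers were slightly higher in Yap-/- organoids. Paneth cell markers were higher for 11 of 11 members, 3 of them at least 2-fold, with a median of 0.70; the antimicrobial ribonuclease gene Ang4 was 2.20-fold and the lectin gene Itln1 2.19-fold higher, and Gm15284, named after its values were seen, was the other. Alpha-defensin genes, peptides of Paneth cell granules, were higher for 12 of 12, with a median of 0.86. Among those past 2-fold were Defa3 (2.97-fold) and Defa24, the latter named after its values were seen, though these copies share sequence and cannot be told apart with confidence. No goblet marker reached 2-fold, yet 15 of 16 were higher, with a median of 0.38, among them Retnlb at 1.73-fold and Klk1 at 1.59-fold. Tuft cell markers had a median of 0.43 (10 of 10 higher, Sh2d6 by 1.64-fold), and enteroendocrine markers 0.25 (15 of 17, Gcg by 1.65-fold and Nts by 1.43-fold). Enterocyte markers had a median of 0.28 (16 of 20 higher, 0 past 2-fold), with the fatty acid carrier gene Fabp1 at 1.67-fold and sucrase-isomaltase, Sis, at 1.60-fold.

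Crypt base stem cell markers had a median of 0.24, higher for 16 of 18 members. Only Olfm4 passed 2-fold (244 against 501 RPKM), and Msi1 was 1.58-fold higher. Wnt target genes had a median of 0.30 with no member past 2-fold, and Sp5 and Ephb3 were 1.68-fold and 1.50-fold higher. The medians of these lineage, stem cell and Wnt lists were at the 99.98 percentile or above. In the pair of reference libraries the stem cell, Wnt and Paneth medians differed by -0.46, -0.40 and -0.72. The enterocyte, enteroendocrine and tuft medians differed there by 0.54, 0.77 and 0.96, and the goblet and alpha-defensin medians by -0.33 and -2.03. Gaps of about this size or larger thus also occur without full loss of Yap. Both pairs use the same Yap+/- library, so the gaps are not independent. For the stem cell, Wnt, Paneth, goblet and alpha-defensin lists, Yap+/- was the lower library by the median in both pairs. For these lists, low levels in the Yap+/- library are not told apart from a rise with loss of Yap.

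Proliferation did not separate the pair. Cell cycle genes had a median of 0.06 (percentile 68.6), 0 of 23 members past 2-fold, and Mcm6 and Plk1 furthest apart at 1.19-fold and 1.15-fold. Hippo pathway components (median 0.02, mean -0.03), p53 targets (median 0.01, mean -0.03), Notch pathway genes (0.07) and housekeeping genes (0.07) also stayed within random lists. The integrated stress response list had a median of -0.24, with 13 of 16 members lower and 0 past 2-fold. Chac1 was 1.73-fold and Gdf15 1.82-fold lower. The immediate early and heat shock list had a median of -0.27, with Atf3 2.23-fold and Hspa1b 2.87-fold lower. Of its 12 members only Hspa1b, which has a near-identical copy, passed the 2-fold rule. Interferon response genes had a median of 0.24 (percentile 99.9), with Bst2 at 4.07 and 7.35 RPKM and Oas1a 1.53-fold higher. NF-kappaB and acute inflammation genes had a median of -0.12 over 6 members, with Ccl20 1.45-fold lower and Nfkbia 1.19-fold higher. Stromal and immune lists had 1 member each above the floor, Vim (3.39 and 3.46 RPKM) and Cd52 (2.09 and 2.51 RPKM), and red blood cell markers had 0. Sex-linked genes had a median of 0.29 over 3 members (percentile 98.6), with Ddx3y at 2.72 and 3.55 RPKM and Kdm5d at 1.15 and 1.68 RPKM. Vim and Cd52 were named after their values were seen.

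Induction of Yap in YapTg organoids asks the reverse question, what excess YAP does to the young organoid. Induced organoids had higher YAP/TEAD targets (list median 1.64), fetal-like genes (2.71) and interferon response genes (1.71). They had lower enterocyte (-1.97), goblet (-1.91) and stem cell markers (-1.12), with Fabp1, Agr2 and Olfm4 among them. The difference was broad. Of 11108 genes at the floor, 650 were at least 2-fold higher and 644 at least 2-fold lower, and 191 and 121 passed 4-fold. Levels correlated at 0.894 across genes, against 0.974 for the reference pair. There was no library with doxycycline and without the transgene, so effects of the drug and of YAP are not separated here.

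YAP/TEAD target genes were higher in 16 of 19 members at 2-fold, with a median of 1.64. Cyr61 and Amotl2, a secreted matrix protein and an angiomotin that binds YAP, were 59.0-fold (95% interval 49.3 to 71.2) and 69.7-fold higher (61.1 to 80.0). Axl and Ankrd1 had 0 reads in uninduced organoids and 3649 and 1080 in induced ones; placing both at the bound that 3 reads allow left the list median at 1.64. Axl and Ankrd1 were named for their 0 reads, after the values were seen. Among Hippo pathway components 4 of 16 passed 2-fold upward. The DNA-binding partner gene Tead4 was 15.7-fold and the upstream scaffold gene Wwc1 4.84-fold higher, with Tead1 (4.15 to 16.6 RPKM) and Wwtr1 the others, these 2 named after their values were seen.

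The fetal-like and regenerative list stood highest of all, with 13 of 17 members at least 2-fold higher and a median of 2.71. Msln was 34.4-fold and Ly6a 27.5-fold higher, Ly6a reaching 356 RPKM. EGF receptor ligands had 3 of 5 past 2-fold and a median of 1.24: Hbegf was 5.15-fold, Areg 2.96-fold and Ereg, named after its values were seen, 2.64-fold higher. The genes furthest higher overall were low in uninduced organoids. Serpinb9b, a protease inhibitor gene, was at 0.171 and 64.7 RPKM, and Lor, which encodes the cornified envelope protein loricrin, at 0.276 and 54.2 RPKM. Ly6c1 and Psca, both genes of Ly6-type surface proteins, were 244-fold and 142-fold higher, Ly6c1 with a near-identical copy. The ion channel gene P2rx2 was 180-fold higher, and S100a7a, an epidermal calcium-binding protein, had 0 reads without and 4916 with doxycycline, at least 978-fold higher against 3 reads.

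Absorptive and secretory markers were lower. Of 20 enterocyte markers 16 were at least 2-fold lower, with a median of -1.97. Fabp1 was at 1938 RPKM in uninduced and 106 RPKM in induced organoids, 18.3-fold lower, and the trehalase gene Treh was 10.2-fold lower. Of 16 goblet cell markers 15 were at least 2-fold lower, with a median of -1.91, Agr2 by 6.53-fold and Fcgbp by 5.61-fold. Enteroendocrine markers had a median of -0.99, with 7 of 14 past 2-fold. The endocrine progenitor factor Neurog3 was 9.58-fold and the peptide gene Tac1 4.48-fold lower. Among the genes furthest lower overall were the antimicrobial and regenerating-islet genes Reg3a (27.2-fold) and Reg1 (16.5-fold), the ileal bile acid carrier gene Fabp6 (27.7-fold) and the drug-metabolising Cyp3a25 (26.3-fold), the last with close relatives that can share its reads.

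Stem cell markers, Wnt targets and Paneth cell markers were lower too. Of 18 stem cell markers 11 were at least 2-fold lower, with a median of -1.12. Olfm4 was at 424 and 22.0 RPKM, 19.3-fold lower, the water channel gene Aqp4 was 7.14-fold lower, and Lgr5 itself was 6.76-fold lower at 6.15 and 0.910 RPKM. Wnt targets had a median of -0.44. The feedback gene Axin2 was 2.73-fold and Sp5 3.86-fold lower, while Ccnd1, which encodes cyclin D1, was higher at 34.2 and 72.7 RPKM. Paneth cell markers had a median of -0.74, with 3 of 11 past 2-fold: Dll4 (5.61-fold), Wnt3 (5.43-fold) and Ang4 (2.15-fold). Lyz1, the lysozyme gene, was only 1.60-fold lower. Between the reference libraries the Wnt and Paneth medians were of similar size, at -0.40 and -0.72, and the stem cell median was -0.46. The reference pair uses the same uninduced YapTg library, so its gaps are not independent of those with induction. Alpha-defensin genes had a median of -0.55, lower for 12 of 12 but inside the random range at percentile 2.53. Tuft cell markers, with 5 members at the floor, had a median of -0.34 (percentile 16.7). Lgr5, Ccnd1, Ang4 and Lyz1 were named after their values were seen.

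Interferon response genes were higher in 13 of 13 members, 10 of them at least 2-fold, with a median of 1.71. The ubiquitin-like modifier gene Isg15 was 24.8-fold (95% interval 19.5 to 32.1) and the antiviral synthetase-like gene Oasl2 10.7-fold higher. Immediate early and heat shock genes had a median of 1.24 with 9 of 13 past 2-fold, Ier3 by 18.3-fold and Atf3 by 7.31-fold. The integrated stress response list had a median of 0.80. Its 5 members past 2-fold were Chac1 (3.16-fold), Trib3 (3.03-fold), Slc7a11, Psat1 and Ddit3, the last 3 named after their values were seen. The p53 list had a median of 0.34, with the death genes Pmaip1 (4.38-fold) and Tnfrsf10b (3.10-fold) past 2-fold. NF-kappaB genes had a median of 0.52, with only Ccl20 past 2-fold (4.30-fold) and Nfkb2 next at 2.04-fold on the RPKM scale. That median fell within random lists once Ccl20 was left out (0.24, percentile 89.6). Notch pathway genes had a median of -0.70, with Nrarp 3.02-fold and Dll1 2.59-fold lower.

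Cell cycle genes stayed within random lists (median -0.19, percentile 5.16), with 0 of 23 past 2-fold and Tk1 and Aurkb furthest apart at 1.38-fold and 1.34-fold lower. Housekeeping genes had a median of -0.04 and a mean of 0.17, and the actin gene Actb was 3.23-fold higher at 1413 RPKM. Gapdh, a gene with many processed copies, was listed at 4.42 and 3.26 RPKM. Stromal markers had 1 member at the floor, Vim, 5.93-fold lower, and immune markers had 1, Cd52, at 2.79 and 5.76 RPKM. Sex-linked and red blood cell markers had 0. Actb, Gapdh, Vim and Cd52 were named after their values were seen.

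**Figure D2:**
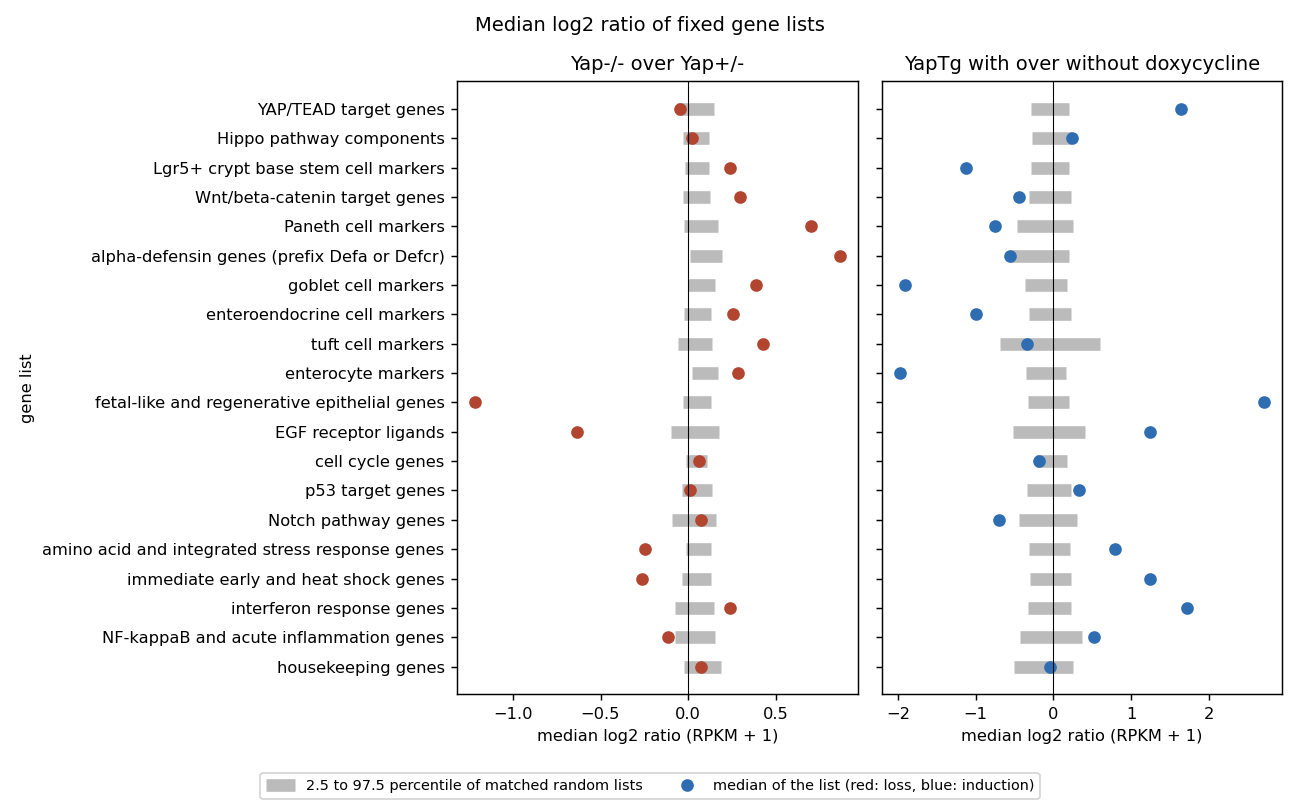
Median log2 ratio of gene lists with at least 3 members at the floor, for Yap loss (left) and Yap induction (right). Grey bars give the range of matched random lists, and the sex-linked list is not drawn. Fetal-like and regenerative genes sit at -1.21 and 2.71, and enterocyte markers at 0.28 and -1.97.

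The Yap+/- and the uninduced YapTg library give a yardstick for differences between organoid lines. They differed at 2-fold in 200 of 10883 genes, 121 higher (60.5%) and 79 lower in Yap+/-. The median over all genes was -0.11, so this pair is read relative to that shift. After median-ratio scaling the split was 173 higher (74.2%) and 60 lower, and after upper-quartile scaling 156 (71.2%) and 63. Y-linked genes set the pairs apart: Eif2s3y had 961 reads in Yap+/- and 1429 in Yap-/- organoids and Ddx3y 718 and 1114, while both had 0 reads in each YapTg library. Eif2s3y and Ddx3y were named here after their values were seen.

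All 12 alpha-defensin genes were at least 2-fold lower in Yap+/- organoids, with a median of -2.03; Defa21 was 15.5-fold and Defa24 2.65-fold lower. Paneth cell markers had a median of -0.72, and Lyz1, Itln1 and Gm15284 passed 2-fold. Enterocyte (0.54), enteroendocrine (0.77) and tuft cell markers (0.96) were higher in Yap+/- organoids, Chga by 2.20-fold. Cell cycle genes had a median of -0.51 and were lower for 23 of 23. YAP/TEAD targets (-0.12), Hippo components (-0.22), interferon genes (-0.13), EGF receptor ligands (0.03, mean -0.00), Notch genes (-0.28), integrated stress response genes (0.10), NF-kappaB genes (0.08) and housekeeping genes (0.04, mean -0.05) stayed within random lists. Fetal-like genes (0.13), p53 targets (0.27), immediate early genes (0.17) and goblet markers (-0.33) lay outside by small amounts. The fetal-like median thus differed far less between the reference libraries than with loss (-1.21) or induction (2.71). Lyz1, Itln1, Gm15284, Defa21, Defa24 and Chga were named in this pair after their values were seen.

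Most genes lower with loss were higher with induction, and fewer of those higher with loss were lower with induction. The comparisons share no library. Among 10533 genes at the floor in both, 38 of the 53 genes lower with loss (71.7%) were higher with induction, against 2.39 for independent lists. The 38 include Yap1 itself, whose directions the design set, and the near-identical Sprr2a2 and Sprr2a3 as separate genes. Of 35 genes higher with loss 12 were lower with induction, against 2.12. This count was 7 after median-ratio scaling. Only 2 were higher and 6 lower in both, against 1.58 and 3.22. The ratios correlated negatively across genes (Pearson -0.47, Spearman -0.43), and genes are not independent replicates.

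Lower with loss and higher with induction, the clearest were Sprr2a2, Sprr2a3, Msln, Plaur, Sprr1a and Yap1 itself. Plaur, the urokinase receptor gene, was 5.57-fold lower with loss and 11.8-fold higher with induction. Sprr1a was 2.93-fold lower and 3.57-fold higher, and Sprr2a2 7.70-fold lower and 6.60-fold higher. Sprr1a was at 29.0 RPKM in uninduced YapTg, near its 29.9 RPKM in Yap-/- organoids, against 87.5 RPKM in Yap+/-. Msln and Plaur, at 5.41 and 7.25 RPKM uninduced, were nearer to Yap+/- (5.15 and 10.5 RPKM) than to Yap-/- (0.286 and 1.88 RPKM). Uninduced Sprr2a2, at 15.6 RPKM, lay between Yap+/- (46.6 RPKM) and Yap-/- (6.05 RPKM). Sprr2a3 reached 1120 RPKM in induced organoids from 211 RPKM, and 90.5 RPKM was left without Yap. In the other direction were Nox1, Enpp7, G6pc, Ang4, Olfm4 and Gkn3. Ang4, Olfm4 and Gkn3 were at 414, 424 and 5.72 RPKM in uninduced YapTg. That is nearer to Yap-/- (482, 501 and 6.84 RPKM) than to Yap+/- (220, 244 and 2.85 RPKM). Enpp7 and G6pc, at 9.38 and 16.8 RPKM uninduced, were nearer to Yap+/- (7.86 and 17.3 RPKM) than to Yap-/- (19.8 and 41.3 RPKM). Uninduced Nox1, at 5.21 RPKM, lay between Yap+/- (2.61 RPKM) and Yap-/- (9.22 RPKM). The glucose-6-phosphatase gene G6pc was 2.39-fold higher with loss and 18.3-fold lower with induction, and the gastrokine gene Gkn3 2.40-fold higher and 14.5-fold lower. Nox1 was 3.53-fold higher and 3.45-fold lower, and Enpp7 2.52-fold higher and 3.40-fold lower. Of the genes that went the same way in both, the duodenal iron reductase gene Cybrd1 was 4.79-fold lower with loss, and at 17.4 and 2.18 RPKM without and with induction. Cbr3, a carbonyl reductase gene, was 3.24-fold and 3.99-fold lower. The other 4 lower in both were Fabp6, Btnl6, 2210407C18Rik and AA467197. The 2 higher in both were the predicted genes Gm17379 and Gm17579. These 8 genes were named after their values were seen.

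**Figure D3:**
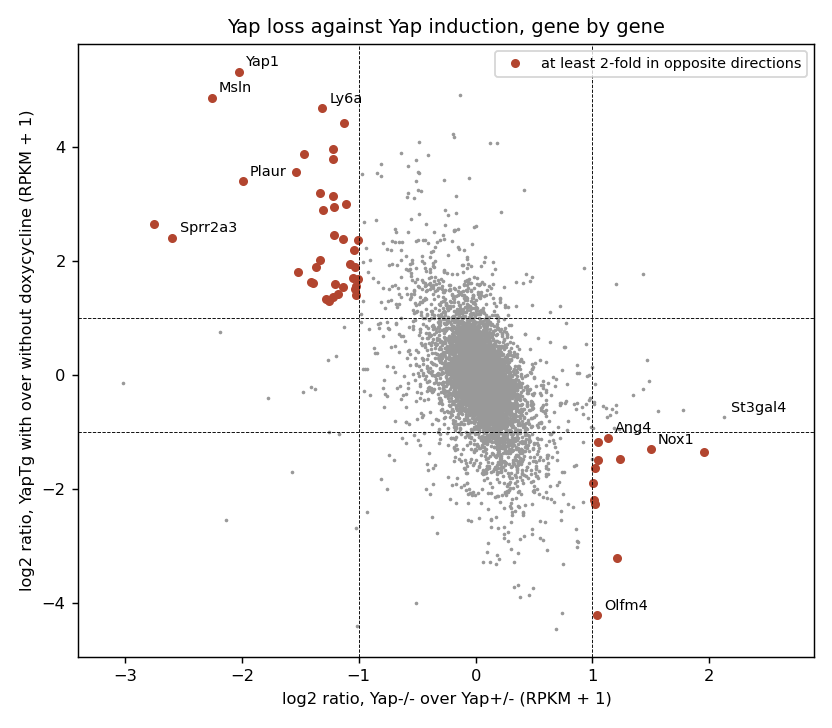
Each dot is a gene, with its log2 ratio for Yap loss on the x axis and for Yap induction on the y axis, on the RPKM plus 1 scale. The 50 genes at least 2-fold apart in opposite directions are in red, 38 at the upper left and 12 at the lower right.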

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

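The restriction to established gene names and the removal of the chromosome of Yap1 were chosen only after the results were seen; the other alternatives were planned. With a pseudocount of 0.1, the genes at least 2-fold apart numbered 178 for Yap loss, 411 for the reference pair and 92 for opposite directions. With a pseudocount of 5 they numbered 39, 99 and 13, and 673 for induction. At a 4-fold threshold they numbered 9 for loss, 312 for induction, 35 for the reference pair and 4 for opposite directions. A floor of 5 RPKM left 32 genes in opposite directions, and established names alone left 131 genes in the reference pair. These follow from how each setting is built: a smaller pseudocount lets low genes pass, and the other settings remove genes. Removing the floor moved nothing, since a pseudocount of 1 already demands 1 RPKM for a 2-fold ratio.

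Loss gave fewer genes than the reference pair under every alternative run on both. It gave 97 under median-ratio and 94 under upper-quartile scaling, against 233 and 219. Its split of 36 higher and 61 lower is less firm: 20 and 19 with a pseudocount of 5, 17 and 48 with established names. Genes in opposite directions outnumbered those in the same direction under every alternative, at the least by 13 against 4 and 4 against 1. The 12 genes higher with loss and lower with induction are the weaker part, with 7 after median-ratio scaling, 3 with a pseudocount of 5 and 0 at 4-fold. Removing the chromosome of Yap1 left 91 genes for loss and 48 in opposite directions.

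Over 62 list medians and 368 alternatives, 353 kept their place below, inside or above the random range. Another 10 moved outside it, 5 moved inside it and 0 reversed a median that stood apart. A median inside the range could change sign and still count among the 353. Median-ratio scaling shifts a list and its random lists nearly alike, so that alternative could hardly change a side. The YAP/TEAD targets moved outside for Yap loss with a pseudocount of 5 (median -0.0398, percentile 2.02), and the cause was not tested. Those that moved inside were the NF-kappaB list in loss and in induction and the Hippo components in induction. Alpha-defensin genes in induction moved just outside under 4 alternatives. The housekeeping median in induction, -0.04, was 0.43 with a floor of 5 RPKM, so its sign is not fixed. No paired analysis was possible because each group has 1 library. Depth limits low genes: 3 reads in a 1 kb gene are 0.0399 to 0.0668 RPKM.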

Other observations

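The gene families, the single genes named below and the tests of explanations were chosen only after the results were seen. The cell cycle, interferon and immune lists and median-ratio scaling, which some tests use, were fixed beforehand.

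Gene families outside the fixed lists also parted the libraries. Of 21 epidermal differentiation complex genes at the floor, which encode proteins of the cornified envelope of skin, 17 were at least 2-fold higher with induction (median 1.38), and 8 of 15 were at least 2-fold lower with loss (median -1.03). Against the uninduced YapTg library, 3 of 15 were at least 2-fold higher in the same Yap+/- library (median 0.25, percentile 99.8). High levels in the Yap+/- library can thus be part of the gap with loss. S100a14 was at 22.4 RPKM in Yap+/- and 9.83 RPKM in Yap-/- organoids, and at 20.9 and 174 RPKM without and with doxycycline. Laminin genes of the basement membrane were higher with induction in 5 of 6 members, with Lama5 at 0.722 and 17.2 RPKM. With loss, Lamb3 was lower, at 9.83 against 3.93 RPKM. Of 11 Ly6 family genes 8 were higher with induction, and of 14 keratin genes 12 were. Krt7 was at 31.5 and 372 RPKM, while Krt9, Krt14, Krt16, Krt17 and Krt42 had nearly the ratio of the far more abundant Krt19, with which they share sequence. Of 90 genes for drug and xenobiotic metabolism 67 were at least 2-fold lower with induction (median -1.54), and of 5 Reg family genes 4 were. These directions held under the other scalings.

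Several genes also differed between the loss pair and the YapTg pair. Isx was at 10.6 RPKM in Yap+/-, 0.429 in Yap-/-, 72.2 in uninduced and 65.6 in induced organoids. Bcmo1, a gene that Isx is known to repress, was at 48.6, 125, 2.36 and 1.64 RPKM in the same order, and Scarb1, another, at 11.3, 32.2, 4.83 and 3.94 RPKM. Cyp1a1 was at 14.4 RPKM in Yap+/- and at 0.255 and 0.665 RPKM in the YapTg libraries, and at 0.0564 RPKM in Yap-/- organoids. Cwc22 was at 2.56 and 2.23 RPKM in the loss pair and at 15.2 and 14.8 RPKM in the YapTg pair. Cd74 was at 0.361 and 0.408 RPKM against 4.31 and 1.92 RPKM. Strain and region of gut are not given for the libraries, and no explanation was tested for these values.

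St3gal4 and Tmem45b, both at least 2-fold higher in Yap-/- organoids, lie on the chromosome of Yap1 within 30 Mb of it in GRCm38. A stretch of donor-strain chromosome around the targeted locus could carry such differences. Within that window 2 of 121 genes differed at 2-fold, against 84 of 10367 elsewhere. The odds ratio was 2.06 (95% interval 0.242 to 7.83), but the 2 changed genes in the window are the 2 that prompted the count. It therefore restates the observation, and donor-strain sequence and loss of Yap both stay open. St3gal4 was at 52.2 RPKM in Yap+/-, 230 in Yap-/-, 117 in uninduced and 69.7 in induced organoids. Tmem45b was at 33.5, 77.4, 88.9 and 46.0 RPKM in the same order. Both genes were thus lowest in the Yap+/- library and lower with induction.

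Histone genes and Lars2 were lower in Yap-/- than in Yap+/- organoids: Lars2 was at 544 against 158 RPKM, and 12 replication-dependent histone genes had a median of -0.74, with 3 at least 2-fold lower and 9 in neither direction. Fewer cells in S phase would lower the cell cycle list too, but its median lay at percentile 68.57, and its lowest member, Foxm1, had a log2 ratio of -0.10. A larger share of RNA without a poly(A) tail in the Yap+/- library stays open. Against the uninduced YapTg library the histone median also lay at percentile 100.0, with Lars2 at 110 RPKM, but both gaps use the same Yap+/- library, so this does not single out that explanation. Most of these histone genes were near the floor.

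Interferon response genes were higher in induced organoids by a median of 1.71. Relative to all genes under median-ratio scaling the median was 1.75. Scaling shifts all genes nearly alike, so a place relative to all genes could not test it. Median-ratio scaling moved the median over all genes only from -0.04 to -0.004, which is small beside 1.71. Immune cells stay open: the reads of 13 immune markers summed to 0.875 times those of the uninduced library (95% interval 0.799 to 0.958), but 12 lay below the floor, and Cd52, the other, was 2.06-fold higher. Doxycycline itself cannot be told apart from induced Yap, because no library had the drug without the transgene.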
